A study of Homo sapiens with 9 samples.

How the data were processed

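Messenger RNA was measured in 9 libraries of MDA-MB-231, an established human breast cancer cell line of mesenchymal character that lacks oestrogen receptor. The cells had been kept in plain medium (No CM), in medium conditioned by untreated MDA-MB-231 cells (Cont CM), or in medium conditioned by MDA-MB-231 cells made senescent with nocodazole, a drug that depolymerizes microtubules (TIS CM, for therapy-induced senescence). Each of the 3 groups held 3 libraries. Per the labels, the senescent donor cells received 100 ng/ml nocodazole for 72 h. The sample labels give 72 h in conditioned medium and the series design text gives 48 h, and nothing in the file settles which applies. Sample replicates are numbered in the labels, but nothing states that they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

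Per the labels' protocols, polyadenylated RNA was captured with poly-T beads, fragmented, and converted to complementary DNA with random hexamers before adapters were ligated. The submitters' processing notes list fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and genome build hg38, without roles or settings. The authors deposited FPKM, fragments scaled by gene length and by library size, for 58735 genes in every library, with the gene length, position and biotype. Of these genes, 29086 were listed at 0 in every library. Gene identifiers in the deposited table matched GENCODE 29 (Ensembl 94), and the coordinates given are those of the table. Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated, and genes with near-identical copies are uncertain.

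The deposited FPKM times gene length was a whole multiple of a single step in each library for 100% of values, within 0.01 of a whole number, so fragment counts could be recovered. They summed to between 32636708 and 39189036 per library, and 1 fragment on a gene of 1 kb was worth between 0.0255 and 0.0303 FPKM. The library sizes implied by the steps lay between 99.28% and 101.34% of the summed fragments and equalled median-of-ratios size factors of the recovered fragments, so the deposited FPKM were already scaled in that way. Such scaling assumes that most genes do not change, and FPKM depend on the gene length the authors used.

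Genes with a mean FPKM of at least 0.5 over the 9 libraries were tested, which left 13912 genes, 11276 of them protein coding. Values were put on the scale log2(FPKM + 0.5), which understates the change of low genes, and all fold changes are on that scale. Limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with group means, an intensity trend and moderated variances, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes in each comparison. A gene was called at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9.

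Before the data were examined, 40 gene lists were fixed. They covered SASP (senescence-associated secretory) cytokines and chemokines, SASP proteases and growth factors, NF-kB, type I interferon, STAT3, TGF-beta, YAP/TAZ, ERK and AP-1, hypoxia, heat shock, ATF4, unfolded protein, NRF2, metallothionein, FOXO and p53 responses, antigen presentation, immune checkpoint ligands, G1/S, G2/M, cell cycle arrest, mesenchymal, epithelial and stem cell markers, extracellular matrix, integrins, glycolysis, cholesterol and fatty acid synthesis, lysosome and autophagy, tubulins, MYC and ribosome biogenesis, ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, replication-dependent histones, and markers of fibroblasts, immune cells, endothelium and luminal breast epithelium. Lists with at least 5 tested members, 37 of the 40, were tested with camera, which compares a list's genes with all others, at a preset correlation between genes of 0.01. Adjustment ran over 37 lists in 3 comparisons, 111 tests. Camera with an estimated correlation and fry were run beside it. Where counts of list members called are printed, they are given over all genes and adjusted over the list alone.

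The named genes followed a rule fixed at the same time. In each comparison they are the protein-coding genes called, with a mean of at least 1 FPKM in the higher group and no overlap between groups, and of these the 12 with the largest rise and the 12 with the largest fall. Up to 4 tested members per direction of each list, all tubulins and a fixed set of senescence genes were added, with CDKN1A, CDKN2A, LMNB1, MKI67, IL6, CXCL8, IL1A, IL1B and GLB1 among them. Some genes that the rule names are not reported here. CDKN2A fell below the expression filter and is not used here.

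The alternatives were another pseudocount, other filters on low values, protein-coding genes only, 3 other scalings, voom on the recovered fragments, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, and removal of each library's trend with GC content and gene length. The last was added after the data were seen. Every column of values in the table belonged to a labelled sample. Simulated data with the spread of the real libraries were used to test the scripts for TIS CM against Cont CM over 13912 genes. Limma recovered 33 of 67 genes changed by 1.25-fold, 51 of 67 changed by 1.5-fold and 62 of 66 changed by 2-fold, with 7 false calls among 153.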

Results

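The series asks what the medium of therapy-induced senescent breast cancer cells does to cells of the same line. Transcript levels were compared in MDA-MB-231 cells kept in plain medium (No CM), in medium conditioned by non-senescent cells (Cont CM) and in medium conditioned by nocodazole-induced senescent cells (TIS CM), with 3 libraries in each group. Between 32636708 and 39189036 fragments per library fell on genes, and between 22637 and 23295 genes had a value above 0. The 10 most abundant genes took between 4.34% and 4.8% of fragments. Mitochondrial genes took 2.39% ± 0.68 of fragments in No CM, 3.03% ± 0.26 in Cont CM and 3.02% ± 0.06 in TIS CM (SD, n = 3).

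The first principal component held 30.4% of the variance and ordered the groups, with No CM between -14.8 and -10.85, TIS CM between -3.05 and -1.08, and Cont CM between 11.88 and 17.78. The second held 17.6% and set Cont CM replicate 1, at -19.32, apart from Cont CM replicates 2 and 3, at 13.44 and 7.62. Across genes, Cont CM replicate 3 correlated less with Cont CM replicate 1 (r = 0.9888) than with the TIS CM libraries (r between 0.991 and 0.9916). With Cont CM replicate 2 it had r = 0.9931. Cont CM replicate 2 stood apart in its trend with GC content and gene length, which held 17.7% of the variance of its values around the gene means (r = -0.41 with GC content) against between 0.6% and 5.8% in each of the other 8 libraries.

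**Figure D1:**
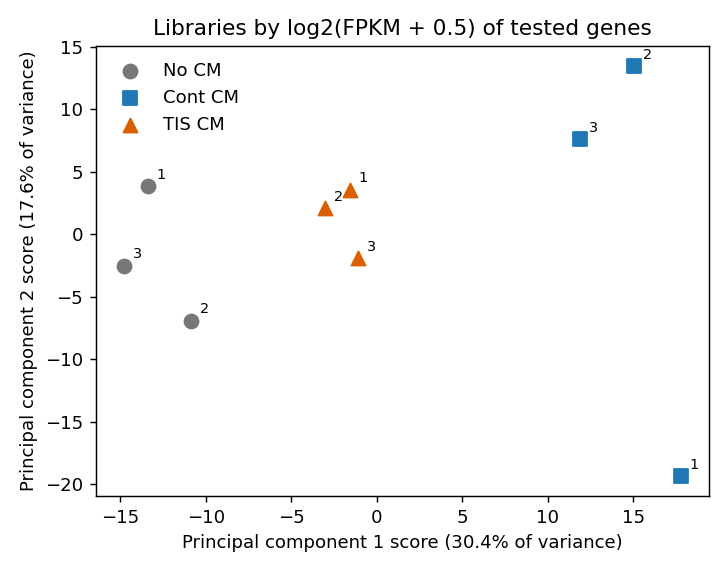
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 0.5) over the tested genes, with each axis labelled by its percent of the variance and each point by its replicate number. The 3 TIS CM libraries lie between No CM and Cont CM on the first component, and Cont CM replicate 1 lies at -19.32 on the second.

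The comparison of TIS CM with Cont CM asks what senescence of the donor cells adds to, or takes from, the effect of conditioned medium. Transcripts of the interleukin-1 cytokines were lower in TIS CM. IL1A (chromosome 2, 112773915 to 112784590) stood at 36 ± 2.17 FPKM in Cont CM and 16.8 ± 1.76 in TIS CM (SD, n = 3), and fell 2.11-fold (log2 fold change -1.08, SE 0.08, limma adjusted p = 0.000675). IL1B fell 1.55-fold, from 27.3 ± 2.67 to 17.4 ± 1.73 FPKM, and the hyaluronan synthase gene HAS2 fell 1.62-fold, from 3.07 ± 0.57 to 1.68 ± 0.103 FPKM. In the other direction, the galectin gene LGALS12 (chromosome 11, 63506084 to 63516774) rose 1.9-fold, the transcription factor gene IRX3 1.58-fold and LFNG, which encodes a glycosyltransferase acting on Notch receptors, 1.59-fold. For each of these 6 genes the TIS CM level lay between the No CM and Cont CM levels, for example 7.64, 16.8 and 36 FPKM for IL1A and 7.57, 3.04 and 1.36 FPKM for LGALS12 in No CM, TIS CM and Cont CM.

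**Figure D2:**
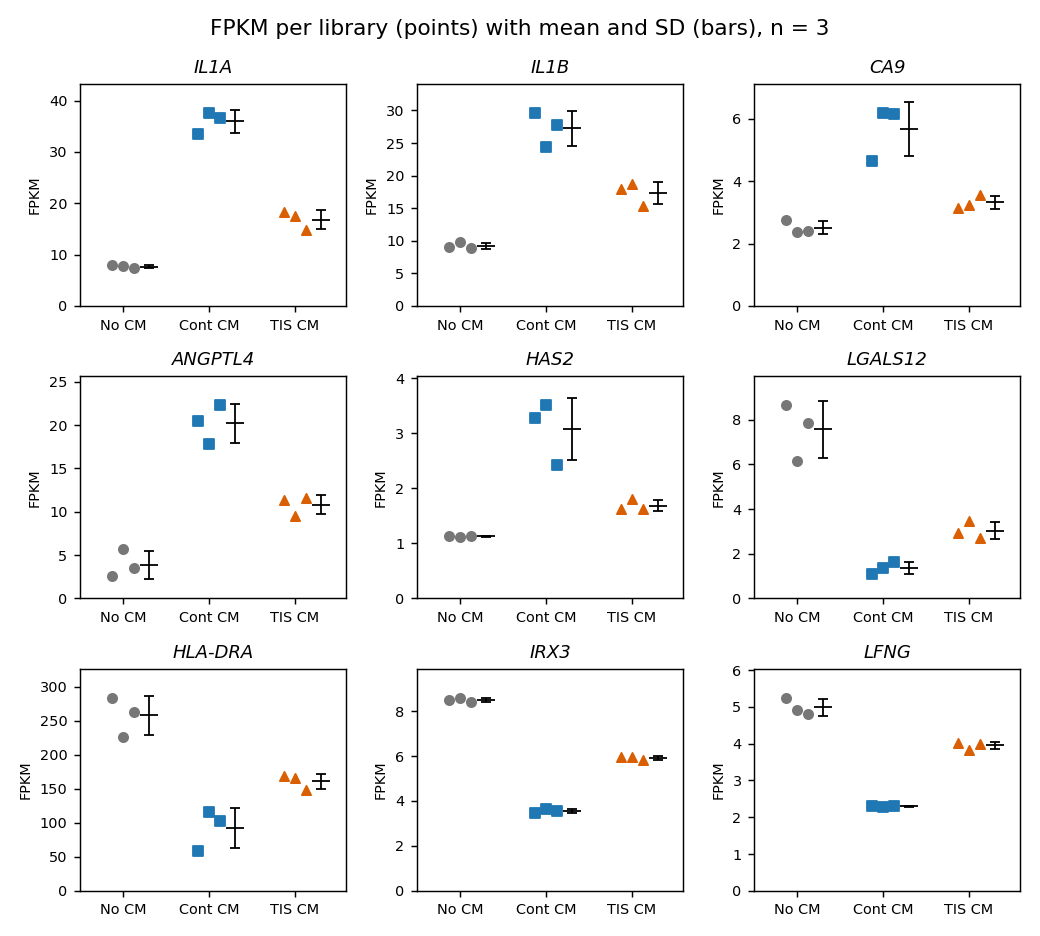
FPKM of 9 genes in each library, shown as points by group, with the mean and SD of the 3 libraries drawn beside them as a bar. All axes start at 0, and for each gene the TIS CM mean, such as 10.8 FPKM for ANGPTL4, lies between the No CM and Cont CM means, 3.91 and 20.2 FPKM for that gene.

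Limma called 404 genes higher and 219 lower in TIS CM than in Cont CM among 13912 tested, 64.8% of the calls higher, and 42 of the 623 exceeded a 1.5-fold change. Among the most raised were also HLA-DPB1, RARRES3, SEMA6B, PLEKHS1, the secreted protease HTRA3, the lysosomal protease CTSD, MMP15 and FPR1, by between 1.53 and 1.79-fold. U2AF1L5, raised 1.74-fold, is a near-identical copy of U2AF1 and its value is uncertain. Among the most lowered were also ESM1, the hypoxia marker CA9, FLI1, TAGLN3, ADAMTS6, VGLL3 and NEXN, by between 1.41 and 1.63-fold.

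Of 17 tested SASP cytokines and chemokines, 1 rose, 3 fell and 13 did not pass, and 1 rose and 6 fell when adjusted over the list alone. CSF1, a growth factor for macrophages, rose 1.41-fold, and camera gave the list as lower (median log2 fold change -0.12, adjusted p = 0.0389, and adjusted p = 0.525 with an estimated correlation). IL6 had a log2 fold change of -0.57 with SE 0.2 (limma adjusted p = 0.134) and stood at 98.51 FPKM in Cont CM replicate 1 against 52.29 and 53.57 in the other Cont CM libraries. Without Cont CM replicate 1 it passed (log2 fold change -0.27, limma adjusted p = 0.0318). The hypoxia list was lower (median -0.13, camera adjusted p = 0.00151, and adjusted p = 0.404 with an estimated correlation), with 1 of 25 members higher, 3 lower and 21 not passing. When adjusted over the list alone, 1 hypoxia gene was higher and 9 were lower. CA9 and LOX, which crosslinks collagen, fell, and the mTOR inhibitor DDIT4 rose 1.35-fold. YAP/TAZ targets were lower (median -0.1, camera adjusted p = 0.039, and adjusted p = 0.525 with an estimated correlation), with DLC1 the only call among 22, over all genes and adjusted over the list alone. The FOXO list was lower (median -0.07, camera adjusted p = 0.0433, and adjusted p = 0.353 with an estimated correlation), with TXNIP the only call among 16 and 3 lower when adjusted over the list alone.

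Antigen presentation genes were higher, with 18 of 19 fold changes above 0 (median 0.22, camera adjusted p = 1.05e-06, and adjusted p = 0.404 with an estimated correlation). Limma called 4 of them higher and 15 did not pass, and 10 were higher when adjusted over the list alone. HLA-F rose 1.5-fold, while HLA-DRA, a class II chain, stood at 92.5 ± 29.6 FPKM in Cont CM and 161 ± 11.4 in TIS CM (limma adjusted p = 0.0574). Cytosolic ribosomal proteins were higher by a small amount, with 70 of 76 fold changes above 0 (median 0.09, camera adjusted p = 2.79e-07, and adjusted p = 0.591 with an estimated correlation), and 7 members were called, RPL41 and RPS19 among them. Nuclear oxidative phosphorylation genes were higher too, with 39 of 43 above 0 (median 0.11, camera adjusted p = 8.13e-05, and adjusted p = 0.525 with an estimated correlation), and COX8A and CYC1 were called. Adjusted over the list alone, 9 ribosomal and 6 oxidative phosphorylation members were higher.

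NRF2 targets, genes of the response to oxidants, were higher (median 0.12, camera adjusted p = 0.00235, and adjusted p = 0.353 with an estimated correlation), and 5 of 21 rose, among them NQO1 by 1.33-fold and OSGIN1, with 9 higher when adjusted over the list alone. The unfolded protein list was higher (median 0.13, camera adjusted p = 0.00483, and adjusted p = 0.639 with an estimated correlation), with SDF2L1 and CRELD2 called among 19, over all genes and adjusted over the list alone. Of 27 ATF4 targets, which serve amino acid uptake and synthesis, 4 rose, including PSAT1 and SLC7A5, 1 fell, ATF3, and 22 did not pass, and 6 rose and 1 fell when adjusted over the list alone (median 0.08, camera adjusted p = 0.0389, and adjusted p = 0.6 with an estimated correlation). G2/M genes were higher by a median of 0.06 (camera adjusted p = 0.024, and adjusted p = 0.741 with an estimated correlation), with BIRC5 and CCNA2 called among 34 and 3 higher when adjusted over the list alone. Luminal breast epithelial markers were higher (median 0.12, camera adjusted p = 0.0328, and adjusted p = 0.353 with an estimated correlation), with SPDEF called among 7 and 2 higher when adjusted over the list alone.

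The remaining 25 lists did not pass camera, with adjusted p between 0.0707 and 0.989. Among them were members called in opposite directions, such as ID1, ID3 and SMAD6, targets of BMP signalling, which rose by between 1.39 and 1.4-fold, and SMURF2, which fell, on the TGF-beta list, which held 3 higher and 2 lower, and 3 and 6 when adjusted over the list alone. In the matrix list, whose median of 0.07 and camera direction differed in sign, 2 of 25 rose, such as COL1A2, and 4 fell, such as COL17A1 and TNC, against 7 higher and 6 lower when adjusted over the list alone. Of 20 mesenchymal markers, S100A4 rose and LOX, CALD1 and TNC fell, with 1 higher and 5 lower when adjusted over the list alone. The STAT3 list held 1 higher and 1 lower among 16, and 6 and 2 when adjusted over the list alone. Of 9 tubulin genes limma called 0, with 1 at an unadjusted p under 0.05 and 0 called by voom (median 0.03), and 0 passed when adjusted over the list alone. The senescence genes CDKN1A, LMNB1, MKI67, CXCL8 and GLB1 did not pass, with log2 fold changes of -0.03, 0.24, -0.04, -0.16 and 0.13. Without Cont CM replicate 1, LMNB1 passed (log2 fold change 0.17, limma adjusted p = 0.0321).

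The TIS CM against Cont CM counts depended on single libraries and on scaling. Without TIS CM replicates 1, 2 or 3 the calls were 7 higher and 4 lower, 20 and 5, and 58 and 25, and without Cont CM replicates 1, 2 or 3 they were 675 and 409, 67 and 32, and 296 and 152. Leaving out No CM replicates 1, 2 or 3 gave 217 and 122, 237 and 122, and 242 and 113. Only 11 genes were called in all 6 omissions of a TIS CM or Cont CM library, with IL1A, IRX3 and LFNG among them. Of the 51 genes named here as called, 48, 47 and 31 lost the call without TIS CM replicates 1, 2 and 3, and 1, 35 and 10 without Cont CM replicates 1, 2 and 3, none with a change of sign. IL1B lost it without TIS CM replicate 1 (limma adjusted p = 0.0599). Limma on the 6 libraries alone called 23 higher and 10 lower, the replicate number as a block left 95 and 31 and no filter 128 and 79, while voom called 625 and 460 and protein-coding genes alone 617 and 378. Fold changes correlated with GC content across genes, which are not independent replicates (r = 0.33). The median GC content was 58.9% in the genes called higher and 42.7% in those called lower, against 48.5% over the tested genes. Their median lengths were 3501 and 6297 bases. Removal of each library's trend with GC content and length, a setting added after the data were seen, left 92 higher and 58 lower, of which 84 and 48 were among the original calls. With FPKM rescaled to equal library sums the split was 284 higher and 395 lower, 41.8% higher, and with quantile normalization 310 and 273, 53.2% higher. Of the 12 lists called, the antigen presentation, hypoxia, NRF2, ribosomal and oxidative phosphorylation lists kept their camera calls in all 6 omissions. Without Cont CM replicate 1 the cytokine, G2/M, YAP/TAZ, ATF4, unfolded protein and FOXO lists gave adjusted p of 0.18, 0.565, 0.154, 0.142, 0.114 and 0.0537. The medians of the G2/M, ATF4 and unfolded protein lists then went from 0.06, 0.08 and 0.13 to 0.01, 0.01 and 0.05, so these rest largely on that library. The medians of the cytokine, G2/M and ATF4 lists were -0.19, 0.1 and 0.05 without Cont CM replicate 2. That of the G2/M list was 0.03 without TIS CM replicate 1. The cytokine list gave adjusted p of 0.0551 without Cont CM replicate 3 and 0.0654 without TIS CM replicate 3. Without TIS CM replicate 1 the G2/M, YAP/TAZ, ATF4, FOXO and luminal lists gave adjusted p of 0.144, 0.058, 0.0935, 0.0778 and 0.058. Without TIS CM replicate 2 the YAP/TAZ and luminal lists gave 0.0511 and 0.101 as adjusted p, and without TIS CM replicate 3 the YAP/TAZ and FOXO lists gave 0.0559 and 0.0935. The luminal list gave adjusted p of 0.0598 and 0.0688 without Cont CM replicates 2 and 3, and the FOXO list 0.138 without Cont CM replicate 3. With the trend removed the ATF4, luminal and FOXO lists lost their calls (adjusted p of 0.108, 0.133 and 0.0587). Their medians were then 0.04, 0.09 and -0.07, against 0.08, 0.12 and -0.07 before. Under quantile normalization the G2/M, ATF4, FOXO and luminal lists gave adjusted p of 0.162, 0.0695, 0.0657 and 0.0665, and under scaling to equal library sums the cytokine, YAP/TAZ and FOXO lists 0.0735, 0.055 and 0.0687. With a minimum mean of 2 FPKM the YAP/TAZ and FOXO lists gave 0.0556 and 0.0807 as adjusted p, and in the fit of only the 2 groups 0.0535 and 0.0521.

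The comparison of Cont CM with No CM gives the background effect of medium conditioned by cells that were not senescent. ANGPTL4, a secreted regulator of lipoprotein lipase (chromosome 19, 8363289 to 8374373), rose 4.89-fold, from 3.91 ± 1.61 to 20.2 ± 2.23 FPKM (SD, n = 3, log2 fold change 2.29, SE 0.22, limma adjusted p = 0.000358). IL1A rose 4.48-fold (limma adjusted p = 2.19e-06), and IL1B 2.85-fold. LGALS12 fell 4.32-fold, from 7.57 ± 1.27 to 1.36 ± 0.262 FPKM, the nerve growth factor receptor NGFR 3.45-fold and FOS 3.4-fold. The class II gene HLA-DRA (chromosome 6, 32439842 to 32445046) fell 2.88-fold, from 258 ± 29.2 to 92.5 ± 29.6 FPKM (log2 fold change -1.52, SE 0.21, limma adjusted p = 0.00228).

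Limma called 1081 genes higher and 1191 lower in Cont CM than in No CM among 13912, and 322 of the 2272 exceeded a 1.5-fold change. ADAMTS6, ESM1, HAS2, FLI1, TEX48, PSG9, TNFSF15 and CA9 rose by between 2.04 and 2.39-fold. RARRES3, PLEKHS1, ATOH8, HLA-DPB1, PI16, the iron exporter SLC40A1, SPINK4 and HLA-DOA fell by between 2.4 and 2.71-fold.

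SASP cytokines and chemokines were higher, with 10 of 17 called higher, 1 lower and 6 not passing, and 10 and 1 when adjusted over the list alone (median 0.3, camera adjusted p = 0.000568, and adjusted p = 0.353 with an estimated correlation). TNFSF15 and IL24 rose by 2.07 and 2.01-fold, CXCL8 1.41-fold and IL6 1.78-fold, and CSF1 fell 1.73-fold. Of 25 SASP proteases and growth factors, 10 rose, 3 fell and 12 did not pass, with 12 and 4 when adjusted over the list alone (median 0.28, camera adjusted p = 0.0458, and adjusted p = 0.431 with an estimated correlation). MMP1 and PLAT rose, and IGFBP4 and IGFBP6 fell. Hypoxia genes were higher, with 8 higher and 3 lower among 25, and 15 and 3 when adjusted over the list alone (median 0.16, camera adjusted p = 0.0012, and adjusted p = 0.404 with an estimated correlation), VEGFA by 1.46-fold, while DDIT4 fell. YAP/TAZ targets were higher, with 6 higher, such as ANKRD1, and 1 lower among 22, over all genes and adjusted over the list alone (median 0.08, camera adjusted p = 0.0269, and adjusted p = 0.483 with an estimated correlation). Mitochondrially encoded genes were higher in all 13 signs (median 0.45, camera adjusted p = 0.00151, and adjusted p = 0.653 with an estimated correlation), with MT-ATP8 the only call and 0 adjusted over the list alone. They moved with the mitochondrial share of fragments, which was 3.15%, 2.17% and 1.85% in the No CM libraries and 2.8%, 3.31% and 2.97% in Cont CM. These 13 genes are counted in the share, so the agreement is built in. Their estimated correlation was 0.914, so the 13 signs are far from independent. That share did not pass a 2-sided exact permutation test (p = 0.3), which cannot pass with 3 against 3 libraries, the smallest possible p being 0.1.

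Type I interferon genes were lower, with 14 of 27 called lower, 0 higher and 13 not passing, and 19 lower when adjusted over the list alone (median -0.3, camera adjusted p = 2.79e-07, and adjusted p = 0.353 with an estimated correlation). OASL and IFI35 each fell 1.6-fold and IFIT3 1.41-fold. Of 19 antigen presentation genes 12 fell and 7 did not pass, with 18 lower and 1 higher when adjusted over the list alone (median -0.3, camera adjusted p = 3.71e-08, and adjusted p = 0.353 with an estimated correlation), CD74 by 2.05-fold and HLA-F by 1.92-fold. Fatty acid synthesis genes were lower, with 5 of 14 called, led by the regulator SREBF1 at 1.82-fold and the desaturase SCD at 1.51-fold, and 7 lower when adjusted over the list alone (median -0.2, camera adjusted p = 0.00174, and adjusted p = 0.353 with an estimated correlation). Luminal breast epithelial markers were lower, with 6 of 7 called over all genes and adjusted over the list alone, AGR2 by 2.07-fold (median -0.37, camera adjusted p = 7.25e-05, and adjusted p = 0.215 with an estimated correlation).

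Cell cycle genes were lower by small amounts. Of 34 G2/M genes 7 fell, such as CCNB2 and KIF20A, and 27 did not pass (median -0.1, camera adjusted p = 0.000568, and adjusted p = 0.653 with an estimated correlation), and of 37 G1/S genes 7 fell, such as E2F2 (median -0.08, camera adjusted p = 0.0344, and adjusted p = 0.737 with an estimated correlation). Adjusted over the list alone, 7 were lower in each. The STAT3 list held 7 lower and 1 higher among 16 (median -0.14, camera adjusted p = 0.0476, and adjusted p = 0.353 with an estimated correlation), with SOCS1 and CEBPD lower, and 7 and 2 when adjusted over the list alone. NRF2 targets held 8 lower and 1 higher among 21, over all genes and adjusted over the list alone (median -0.09, camera adjusted p = 0.0403, and adjusted p = 0.516 with an estimated correlation), with OSGIN1 lower and SLC7A11 higher. The unfolded protein list held 2 lower, CRELD2 and CALR, and 1 higher among 19, over all genes and adjusted over the list alone (median -0.17, camera adjusted p = 0.0114, and adjusted p = 0.653 with an estimated correlation). Ribosomal proteins held 6 lower among 76, and 1 adjusted over the list alone (median -0.05, camera adjusted p = 0.0204, and adjusted p = 0.742 with an estimated correlation), and nuclear oxidative phosphorylation 4 lower among 43, and 3 adjusted over the list alone (median -0.09, camera adjusted p = 0.00218, and adjusted p = 0.6 with an estimated correlation).

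The other 21 lists did not pass camera, with adjusted p between 0.067 and 0.989. Some held members called in opposite directions, others members called in 1 direction only, and some counts were low for their size. Over all 13912 tested genes limma called 1081 higher and 1191 lower. In the TGF-beta list 8 rose, such as SMURF2, and 5 fell, such as ID1 by 1.97-fold and ID3 by 1.83-fold. The matrix list held 7 higher, such as COL17A1, and 7 lower, led by COL1A2. Checkpoint ligands held 5 higher, with CD274, which encodes PD-L1, raised 1.55-fold, and 1 lower. The NF-kB list held 4 higher and 2 lower, ERK and AP-1 output 7 and 2, mesenchymal markers 7 and 2, epithelial markers 3 and 5, with CDH1 lower by 2.1-fold, and integrins 3 and 0. Cell cycle arrest genes held 1 higher and 4 lower, with CDKN1C and CDKN2C lower, and p53 targets 3 and 2. Calls, higher and then lower, were 1 and 3 for glycolysis, 0 and 2 for cholesterol synthesis, 4 and 2 for ATF4 targets, 2 and 2 for heat shock, 1 and 2 for lysosome and autophagy, 3 and 0 for MYC and ribosome biogenesis, 0 and 1 for replication-dependent histones, 0 and 3 for stem cell markers and 1 and 0 for FOXO. Adjusted over the list alone, the higher and lower counts were 8 and 6 for TGF-beta, 7 and 8 for matrix, 5 and 2 for checkpoint, 8 and 3 for ERK and AP-1, and 8 and 4 for mesenchymal genes. They were 3 and 1 for integrin, 5 and 2 for ATF4, 3 and 2 for heat shock, 0 and 0 for histone and 3 and 1 for FOXO genes. The other list counts in this paragraph were the same. Of 6 metallothionein and zinc genes limma called 0, with 1 at an unadjusted p under 0.05 and 1 called by voom. Of 9 tubulins, TUBB6, TUBA1A and TUBA4A rose. LMNB1 fell 1.34-fold, while CDKN1A, MKI67 and GLB1 did not pass, with log2 fold changes of 0.24, -0.04 and -0.09. Without Cont CM replicate 1, CDKN1A passed (log2 fold change 0.37, limma adjusted p = 0.00339).

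Markers of other cell types were mostly near 0. Of 10 fibroblast markers 3 were tested, with COL1A2 at 2.53, 1.17 and 1.73 FPKM and PDGFRB at 1.43, 0.989 and 1.44 FPKM in No CM, Cont CM and TIS CM, and of 10 immune markers the highest was CD14, at 4.75, 3.38 and 4.47 FPKM. Of 9 endothelial markers only KDR was tested, at 1.05, 1.31 and 1.2 FPKM. Of 11 luminal breast epithelial markers 7 were tested. ESR1, PGR and FOXA1 were not, at 0.004, 0.001 and 0.005 FPKM in No CM, so the luminal list covers its tested members only. Of these, KRT8, KRT18 and KRT19 are also on the epithelial list.

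The Cont CM against No CM calls were 492 higher and 583 lower without No CM replicate 3, 703 and 774 without No CM replicate 1, 730 and 767 without No CM replicate 2, 745 and 871 without Cont CM replicate 2, and 573 and 669 in limma on the 6 libraries alone. With FPKM rescaled to equal library sums the calls were 862 higher and 1399 lower, 38.1% higher against 47.6% as deposited. The block gave 672 and 789 and no filter 741 and 792. Fold changes correlated with GC content (r = -0.26), with a median GC content of 44.2% in the genes called higher and 56.3% in those called lower. With the trend removed 981 and 1112 were called, 758 and 832 of them among the original calls. In all 6 omissions of a library 950 genes were called. Of the 65 genes named here as called, 6, 5 and 10 lost the call without No CM replicates 1, 2 and 3, and 3, 2 and 4 without Cont CM replicates 1, 2 and 3. The cytokine, interferon, antigen presentation, hypoxia, fatty acid, luminal and mitochondrially encoded lists kept their camera calls in all 6 omissions. The size of the IL6 rise depended on Cont CM replicate 1, without which the log2 fold change was 0.54 and not 0.83 (limma adjusted p = 0.000867), and that of CALR was -0.19 and not -0.31 (0.0259). IL6 lost its call without each No CM library in turn (limma adjusted p of 0.0748, 0.0528 and 0.0728), TEX48 without No CM replicate 3 (0.0532), and PSG9 without No CM replicates 1 and 3 (0.0667 and 0.0637). Without Cont CM replicate 1 the G1/S, G2/M, YAP/TAZ, unfolded protein and ribosomal lists gave camera adjusted p of 0.451, 0.0537, 0.138, 0.0749 and 0.419. Their medians were then -0.01, -0.05, 0.07, -0.07 and -0.02, and the fatty acid median was -0.13. The YAP/TAZ median was 0.13 and 0.14 without Cont CM replicates 2 and 3. The STAT3 median was -0.09 without Cont CM replicate 2. The ribosomal and mitochondrially encoded medians were -0.02 and 0.27 without No CM replicate 3. Without No CM replicate 3 the protease, STAT3, G1/S, NRF2, ribosomal and oxidative phosphorylation lists gave 0.055, 0.0594, 0.0586, 0.055, 0.171 and 0.055 as adjusted p. The protease and NRF2 lists gave adjusted p of 0.0556 and 0.0854 without No CM replicate 2, and the STAT3 and G1/S lists 0.0683 each without No CM replicate 1. The STAT3 list gave 0.0598 and 0.0591 without Cont CM replicates 2 and 3, and the protease list 0.132 without Cont CM replicate 3. The STAT3 call was also lost with a pseudocount of 0.1, a minimum mean of 2 FPKM, quantile normalization, scaling to equal library sums, protein-coding genes only, the replicate number as a block and the fit of only the 2 groups, with adjusted p between 0.0514 and 0.0677, and with the trend with GC content and length removed (median -0.07, adjusted p = 0.129). The G1/S and ribosomal lists gave adjusted p of 0.052 and 0.105 under quantile normalization, the protease list 0.063 in the fit of only the 2 groups, and the NRF2 list 0.054, 0.0507 and 0.0604 with protein-coding genes only, the block and the fit of only the 2 groups.

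The comparison of TIS CM with No CM gives the whole effect of the senescent cells' medium against plain medium. ANGPTL4 rose 2.68-fold, to 10.8 ± 1.13 FPKM, IL1A 2.12-fold (log2 fold change 1.09, SE 0.08, limma adjusted p = 0.00186) and IL1B 1.83-fold. LGALS12 fell 2.27-fold, the secreted protein gene AGR2 1.99-fold, SPINK4 1.92-fold and the adhesion gene CDH1 1.78-fold. Each lay between the No CM and Cont CM levels, with AGR2 at 2.43, 0.992 and 0.911 FPKM in No CM, TIS CM and Cont CM.

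Limma called 56 genes higher and 63 lower among 13912, and 22 of the 119 exceeded a 1.5-fold change. U2AF1L5, of uncertain value as a near-identical copy, and ADAMTS6, CYP1A1, the growth factor CSF2, MARCH4, RGS4, IL24 and the cystine transporter SLC7A11 rose by between 1.39 and 1.82-fold. PI16, SLC40A1, HLA-DOA, ATOH8, PLEKHS1, TRIM29, the water channel AQP1 and SEMA3F fell by between 1.52 and 1.81-fold.

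SASP cytokines and chemokines were higher, with 4 of 17 called higher, 0 lower and 13 not passing, and 6 higher and 1 lower when adjusted over the list alone (median 0.26, camera adjusted p = 3.08e-05, and adjusted p = 0.353 with an estimated correlation). SASP proteases and growth factors held 3 higher among 25, with 9 higher and 1 lower when adjusted over the list alone (median 0.14, camera adjusted p = 0.00171, and adjusted p = 0.353 with an estimated correlation). ATF4 targets were higher, with 3 of 27 called, SLC7A11 among them, and 11 higher and 1 lower when adjusted over the list alone (median 0.13, camera adjusted p = 7.25e-05, and adjusted p = 0.353 with an estimated correlation). Checkpoint ligands held 1 higher among 12, CD274 at 1.27-fold, and 5 adjusted over the list alone (median 0.03, camera adjusted p = 0.037, and adjusted p = 0.443 with an estimated correlation). Under scaling to equal library sums the checkpoint median was -0.02 and the call was lost (adjusted p = 0.0619). Mitochondrially encoded genes were higher in all 13 signs with 0 called by limma, 8 at an unadjusted p under 0.05, 0 called by voom and 0 adjusted over the list alone (median 0.41, camera adjusted p = 1.06e-05, and adjusted p = 0.591 with an estimated correlation). The mitochondrial share of fragments was 2.95%, 3.07% and 3.03% in TIS CM, and did not pass a 2-sided exact permutation test against No CM (p = 0.4), which cannot pass with 3 against 3 libraries, the smallest possible p being 0.1. Of 76 ribosomal proteins limma called 0, with 5 at an unadjusted p under 0.05, 0 called by voom and 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.00741, and adjusted p = 0.741 with an estimated correlation), and the list call was lost under quantile normalization (adjusted p = 0.232) and under scaling to equal library sums (0.106).

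Type I interferon genes were lower, with 4 of 27 called lower, OASL at 1.44-fold among them, and 14 when adjusted over the list alone (median -0.21, camera adjusted p = 1.23e-11, and adjusted p = 0.215 with an estimated correlation). Fatty acid synthesis held 2 lower among 14, SCD at 1.45-fold and SREBF1 at 1.44-fold, and 5 adjusted over the list alone (median -0.11, camera adjusted p = 0.000126, and adjusted p = 0.353 with an estimated correlation). Luminal markers held 2 lower among 7, AGR2 and SPDEF, and 6 adjusted over the list alone (median -0.25, camera adjusted p = 3.37e-05, and adjusted p = 0.215 with an estimated correlation). Epithelial markers held 1 lower among 18, CDH1, and 6 adjusted over the list alone (median -0.1, camera adjusted p = 0.0223, and adjusted p = 0.653 with an estimated correlation). In 3 further lists camera gave lower values while limma called 0 members. These were antigen presentation (median -0.12, adjusted p = 0.000752, and adjusted p = 0.591 with an estimated correlation), STAT3 (median -0.08, adjusted p = 0.0306, and adjusted p = 0.353 with an estimated correlation) and G2/M (median -0.05, adjusted p = 0.0341, and adjusted p = 0.746 with an estimated correlation). At an unadjusted p under 0.05 they held 5, 4 and 2 members, and voom called 1, 0 and 0. Adjusted over the list alone, 1, 0 and 0 were lower. The remaining 24 lists had camera adjusted p between 0.0703 and 0.905, and ID1 and ID3 fell in the TGF-beta list by 1.41 and 1.32-fold, with 2 higher and 2 lower in that list, and 5 and 6 when adjusted over the list alone.

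**Figure D3:**
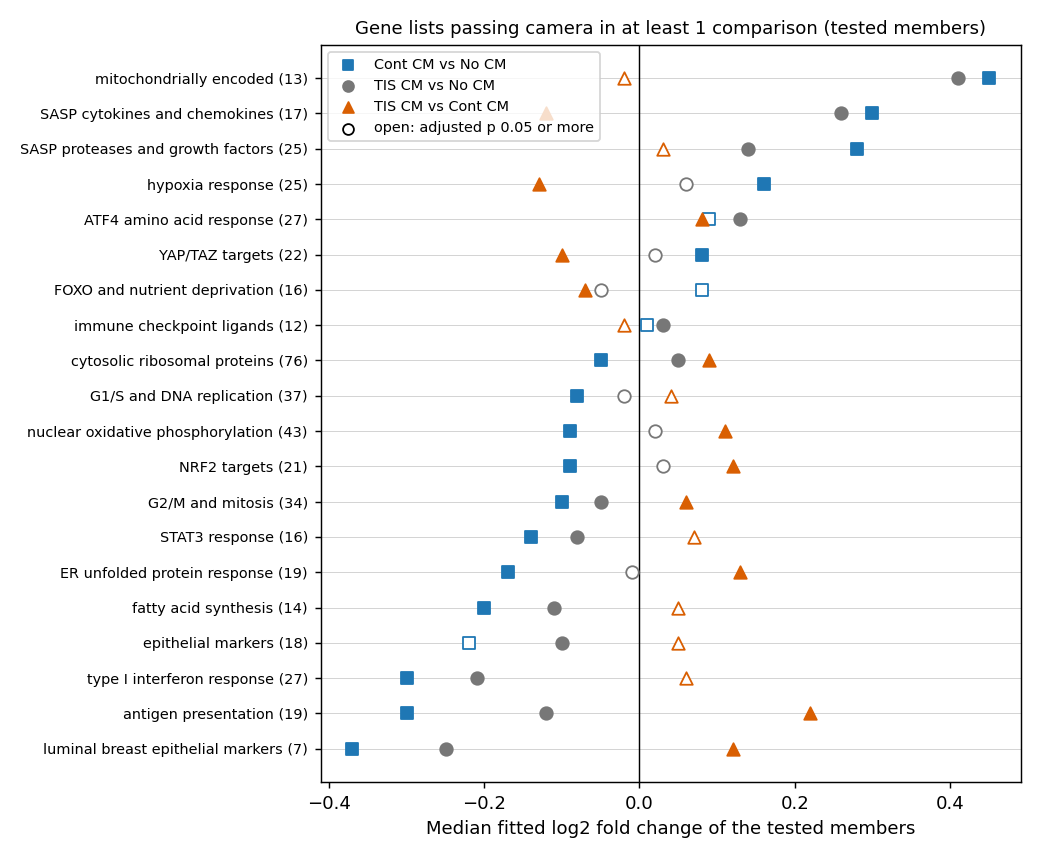
Median fitted log2 fold change of the tested members of the 20 lists that passed camera in at least 1 comparison, with the number of tested members in brackets and open symbols where the adjusted p was 0.05 or more. Antigen presentation genes lay at -0.3 in Cont CM against No CM, -0.12 in TIS CM against No CM and 0.22 in TIS CM against Cont CM.

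The TIS CM against No CM calls were few in the fit of all 9 libraries and depended on single libraries and on the processing. They were 7 higher and 6 lower without No CM replicate 1, 24 and 17 without No CM replicate 2, 6 and 3 without No CM replicate 3, 6 and 3 without TIS CM replicate 1, 6 and 12 without TIS CM replicate 2, and 6 and 3 without TIS CM replicate 3. Without Cont CM replicate 1, which enters only through the shared spread, they were 195 and 170, and without Cont CM replicate 3 they were 34 and 35. In all 6 omissions of a No CM or TIS CM library 7 genes were called, with IL1A, IL1B and SCD among them. Of the 30 genes named here as called, 26, 18 and 26 lost the call without No CM replicates 1, 2 and 3, and 27, 21 and 27 without TIS CM replicates 1, 2 and 3. ANGPTL4 lost it without No CM replicates 1 and 3 (limma adjusted p of 0.0655 and 0.136) and without TIS CM replicates 1, 2 and 3 (0.13, 0.0807 and 0.134). The block left 2 higher and 2 lower and no filter 23 and 23, while limma on the 6 libraries alone called 176 and 155, voom 105 and 140 and protein-coding genes alone 94 and 116. Limma on 6 libraries alone called 23 higher and 10 lower in TIS CM against Cont CM. The fit of all 9 libraries gave the reverse order, with 56 and 63 in TIS CM against No CM and 404 and 219 in TIS CM against Cont CM. The counts thus do not tell which of the 2 groups TIS CM lies nearer to. With FPKM rescaled to equal library sums the TIS CM against No CM calls were 28 higher and 106 lower, 20.9% higher against 47.1% as deposited. The cytokine, protease, interferon, antigen presentation, fatty acid, ATF4, mitochondrially encoded and luminal lists kept their camera calls in all 6 omissions. The checkpoint, STAT3, epithelial and ribosomal lists gave adjusted p of 0.196, 0.058, 0.058 and 0.23 without TIS CM replicate 1. Without No CM replicate 2 the checkpoint and epithelial lists gave adjusted p of 0.0862 and 0.0682, and without No CM replicate 3 the STAT3 and G2/M lists gave 0.0597 each. The G2/M list gave adjusted p of 0.213, 0.0746 and 0.206 without No CM replicate 1, TIS CM replicate 2 and TIS CM replicate 3, and the ribosomal list 0.195 without No CM replicate 1. The checkpoint median was 0.01 and 0.07 without TIS CM replicates 1 and 2. The epithelial median was -0.04 and -0.06 without No CM replicates 2 and 3. Mitochondrially encoded genes had medians of 0.62 and 0.24 without No CM replicates 1 and 3. The G2/M and ribosomal medians were -0.03 and 0.03 without No CM replicate 1, and the ribosomal median was 0.03 without TIS CM replicate 1. The checkpoint list also lost its call with no filter, quantile normalization and the trend removed (adjusted p of 0.0692, 0.067 and 0.0552), and the epithelial list under scaling to equal library sums (0.0715).

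With an estimated correlation camera called 0 of 37 lists in each comparison, the lowest adjusted p being 0.353 in TIS CM against Cont CM and 0.215 in each of the others, with 3, 4 and 7 lists at an unadjusted p under 0.05 in TIS CM against Cont CM, Cont CM against No CM and TIS CM against No CM. In the same order fry, which asks whether a list's genes move on balance one way, called 6, 13 and 8 lists, and its mixed test, for change in either direction, called 29, 34 and 17.

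Genes changed by the 2 conditioned media overlapped. Of the 56 genes higher in TIS CM than in No CM, 50 were also higher in Cont CM, and of the 63 lower genes 62 were also lower, where independent lists would share 4.4 and 5.4. Across genes, which are not independent replicates, the fold changes of the 2 media against No CM had r = 0.63 and a covariance of 0.0252, and unchanged groups simulated against shared controls gave r = 0.5 and a covariance of 0.0072, a difference in covariance of 0.018. The No CM group is too small to be split into parts of 2 libraries, so part of the excess may come from the shared controls.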

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

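The removal of the trend with GC content and length was chosen only after the data were seen. Every other alternative was chosen before. The cause of a change was not tested except where fewer genes or libraries entered the fit.

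Of 404 genes higher and 219 lower in TIS CM than in Cont CM, the counts became 128 and 79 with no filter, 617 and 378 with protein-coding genes only, 95 and 31 with the replicate number as a block, 23 and 10 in a fit of only the 2 groups, 625 and 460 with voom, and 92 and 58 with the trend removed. Scaling to equal library sums gave 395 lower. Leaving out each library gave 7 to 675 higher and 4 to 409 lower. The 12 lists became 0 with an estimated correlation, 6 with fry, and 7 to 13 with a library left out.

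Of 1081 genes higher and 1191 lower in Cont CM than in No CM, the block gave 672 and 789 and the fit of only the 2 groups 573 and 669, and no filter gave 792 lower. Leaving out each library gave 492 to 1332 higher and 583 to 1438 lower. The 16 lists became 0 with an estimated correlation and 10 to 16 with a library left out.

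Of 56 genes higher and 63 lower in TIS CM than in No CM, the counts became 23 and 23 with no filter, 28 and 106 with scaling to equal library sums, 94 and 116 with protein-coding genes only, 2 and 2 with the block, 176 and 155 in the fit of only the 2 groups, and 105 and 140 with voom. Leaving out each No CM or TIS CM library gave 6 to 24 higher and 3 to 17 lower, and leaving out Cont CM replicates 1, 2 and 3 gave 195 and 170, 65 and 74, and 34 and 35. The 13 lists became 0 with an estimated correlation and 8 with fry. The correlation of the fold changes of the 2 media, 0.635, was 0.592 with no filter, 0.722 with protein-coding genes only, and 0.586 to 0.681 with a library left out.

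No named gene or list called in a comparison changed direction under an alternative run, although the median of the checkpoint list in TIS CM against No CM changed sign under scaling to equal library sums. With a library left out, the named genes called lost the call in 172 of 306 values in TIS CM against Cont CM, 30 of 390 in Cont CM against No CM and 145 of 180 in TIS CM against No CM. In the other alternatives they lost it in 136 of 602, 26 of 769 and 53 of 349. Of the 51 in TIS CM against Cont CM, 43 lost it in the fit of only the 2 groups, 28 with the block, and 26 each with no filter and with the trend removed, and of the 30 in TIS CM against No CM, 28 with the block and 20 with no filter.

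The numbers of the replicates were tried as a block but do not pair the samples. After group means were removed, libraries with the same number correlated between -0.187 and 0.084, and 2 of 9 libraries matched best with their own number.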

Other observations

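The class II genes, the positions per list, the simulated positions, the intervals over libraries and the removal of the GC content and length trend were chosen only after the data were seen, and the other tests in this part were chosen before the results they measure. In Cont CM, IL1A and IL1B rose and HLA-DRA and LGALS12 fell against plain medium, and in TIS CM the levels of these genes lay between the others. Of the 404 genes higher in TIS CM than in Cont CM, 328 were lower in Cont CM than in No CM, where independent lists would share 34.6, and of the 219 lower genes 190 were higher, where 17 would be shared. Because Cont CM enters both comparisons with opposite sign, part of this sharing is built in, and the fold changes correlated at r = -0.72 where unchanged groups simulated with the same sharing gave -0.5.

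The first pattern weighed is that the TIS CM libraries lie between No CM and Cont CM. On a line with No CM at 0 and Cont CM at 1 they lay at 0.47, 0.41 and 0.48 (mean 0.46, SD 0.04), at 0.45 with protein-coding genes alone and at 0.51 with the GC content and length trend removed. The SD covers the TIS CM libraries only and leaves out the spread of the ends. With 1 No CM or Cont CM library left out in turn, the mean lay between 0.41 and 0.5. The direction and the ends of the line came from different No CM and Cont CM libraries, and positions simulated at 0, 0.2, 0.8 and 1, with independent genes, were estimated at -0.001, 0.202, 0.799 and 1.001. With unchanged groups the estimate is void, at -43.2 to 9.92 (median 0.56) in 100 simulations, but the product per gene by which it divides was then at most 0.00155, and here it was 0.037. A weaker form of the Cont CM change would leave few genes off the line. In limma 1 gene, the mitochondrial tRNA gene MT-TE, departed from it at the estimated fraction, with an adjusted p of 0.0466, close to the threshold. It stood at 3.54, 6.45 and 10.1 FPKM in No CM, Cont CM and TIS CM. At an unadjusted p under 0.05 there were 1492 genes where chance gives 696. The same test found 190 of 200 genes departing by 2-fold in simulated data, with 7 false, and smaller departures were not simulated. Only 5 of the 623 genes called between TIS CM and Cont CM exceeded a 2-fold change. At fractions of 0.3, 0.4, 0.5, 0.6 and 0.7 the test found 2, 1, 0, 0 and 7 genes, so it barely tells these fractions apart. Departures of 2-fold were thus rare, but whether a weaker form accounts for the smaller changes cannot be decided by this test. That a weaker form accounts for every list is not shown. By camera 8 lists departed from the line with a preset correlation, given below, and 0 with an estimated correlation (adjusted p of at least 0.535). Cont CM replicate 1, which stands apart, is not the cause, as the mean fraction without it was 0.41 (SD 0.03). Of the 623 genes called between TIS CM and Cont CM, 523 (83.9%) stayed called under quantile normalization, so most of these calls do not rest on the deposited scaling. With FPKM rescaled to equal library sums 41.8% of the calls were higher, against 64.8% as deposited. The position itself was not computed under another scaling, so a part played by scaling in it was not tested. Whether the senescent cells released less of a factor, fewer donor cells conditioned the medium or the nutrients were less used was not tested.

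The second is the small rise of ribosomal protein and oxidative phosphorylation genes in TIS CM against Cont CM. If a trend with GC content or length between libraries were the whole cause, removing it would bring the 119 members to 0, but their median was 0.095 before (0.078 to 0.116 over 10000 resamples) and 0.098 after (0.089 to 0.121), with 109 above 0 each time. Limma called 9 of them before and 3 after. Resampling treats the members as independent, and they are not, so the intervals are too narrow. Over the 6 libraries, the difference between group means of the members' median was 0.092 before (95% interval 0.019 to 0.165) and 0.1 after (0.033 to 0.167). Neither value shrank when the trend was removed and the later interval stays above 0, which argues against the trend as the whole cause for these members as a set. Both intervals reach below 0.047, a bound that a rule written beforehand set from the median before removal. They measure the spread of the difference between libraries and not the part of the trend. A part played by the trend would have lowered the values and no lowering was seen, but no interval was computed for that change.

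The third is whether nocodazole carried over with the medium. Free tubulin lowers its own mRNA, so a drug that raises free tubulin would lower tubulin mRNAs, and an arrest in mitosis would raise mitotic genes. The predictions written beforehand put each change at a median log2 fold change of more than 0.3 in size. The 9 tubulins had a median log2 fold change of 0.031 (-0.136 to 0.103) in TIS CM against Cont CM with members on either side of 0. Over the 6 libraries the interval was -0.025 to 0.079. Both intervals exclude a fall of 0.3, which argues against carry-over of the predicted size for these genes. The interval over members reaches below the preset bound of -0.1, although the interval over the 6 libraries stays above it, so a smaller carry-over cannot be told apart from none. The G2/M genes had a median of 0.063 (0.032 to 0.093), but their estimated correlation was 0.506, so this interval is too narrow. The median was 0.01 without Cont CM replicate 1, 0.03 without TIS CM replicate 1 and 0.1 without Cont CM replicate 2. Over the 6 libraries the difference was 0.057 (95% interval -0.113 to 0.228), which lies below 0.3 but reaches above the preset bound of 0.1, so a smaller arrest cannot be told apart from none. Only a rise of the G2/M genes was predicted, although donor cells given the drug for 72 h became senescent. These genes therefore do not test a carry-over that leaves cells without an arrest in mitosis.

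The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05, and in each comparison 1 of the 10 splits, the real one, gave as many genes and as many lists. In TIS CM against Cont CM the real split called 623 genes and 12 lists and the highest other 0 and 10. In Cont CM against No CM they called 2272 and 16 against 1 and 12, and in TIS CM against No CM 119 and 13 against 1 and 8. Every other split mixes libraries of both groups, which puts any difference between the groups into the spread. Their low gene counts are therefore no measure of chance. Mixed splits called up to 10, 12 and 8 lists, so a camera call with a preset correlation does not by itself set a real grouping apart.

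Of 10 tested class II antigen presentation genes, chosen after their values were seen, 10 were lower in Cont CM than in No CM (median -1.08), 3 were higher in TIS CM than in Cont CM with 10 above 0 (median 0.6), and 1 was lower in TIS CM than in No CM with 10 below 0 (median -0.52). The position of TIS CM between No CM and Cont CM, 0.46 over all genes, was 0.52 (SD 0.05) for SASP cytokines, 0.4 (SD 0.08) for antigen presentation, 0.7 (SD 0.11) for type I interferon genes, 0.69 (SD 0.07) for fatty acid synthesis and 0.23 (SD 0.06) for NRF2 targets. Over the 17 lists with at least 5 members called and a root mean square log2 fold change of at least 0.3 in Cont CM against No CM it lay between 0.23 and 0.81. It is not given for lists that changed less, since it divides by that change. Each SD covers the TIS CM libraries only and leaves out the spread of No CM and Cont CM. By camera, 8 lists departed from the line. Ribosomal proteins (median 0.06, adjusted p = 2.53e-08), ATF4 targets (0.08, adjusted p = 1.14e-05), nuclear oxidative phosphorylation (0.06, adjusted p = 0.00315), mitochondrially encoded genes (0.22, adjusted p = 0.00315) and NRF2 targets (0.07, adjusted p = 0.0182) lay higher than the line. Type I interferon genes (-0.09, adjusted p = 7.02e-05), the FOXO list (-0.05, adjusted p = 0.0219) and fatty acid synthesis (-0.03, adjusted p = 0.0439) lay lower. With an estimated correlation 0 lists passed, all with camera adjusted p of at least 0.535, and mixed splits of the libraries also gave camera calls at the preset correlation. These departures therefore do not decide whether a weaker form of the Cont CM change is the whole account.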
